A study of Homo sapiens with 8 samples.

How the data were processed

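Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into DNA that is not shielded by nucleosomes or other proteins. The cells were BJ, an established human foreskin fibroblast line, at passage 19. Per the labels, 8 libraries were prepared as technical replicates by lysing the cells with digitonin in the transposition reaction. They form 1 group, with no treated or control samples, so no comparison between groups of samples was made.

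The authors deposited 2 tables for the whole series. The first gives the start and end of each accessible region (peak), with no score. The second gives the position of each called nucleosome centre (dyad) and an occupancy score. Both are read here as pooled tables with no values per library; that the peaks come from pooled libraries is taken from the label of the deposited table, and whether all 8 libraries entered the nucleosome table is not given in the sources used here. The occupancy score in the deposited table is a fraction between 0 and 1 written in 2 decimals. Per the submitters' processing notes, the genome build was hg19 and the tools included Bowtie2, SAMtools 0.1.19, bedtools 2.20.1, Picard 1.117 and MACS2 2.1.0.20140616, with no role or order stated. The nucleosome caller and the threshold for peaks are not given in the sources used here. The read depth of each library, and of the pool, is unknown, so no precision that depends on read depth can be given. Whether nucleosomes were called only within peaks is not given either. The number of peaks, the share of peaks with a dyad and the occupancy of weak calls can all change with depth and with the calling threshold.

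Positions were used as deposited and are printed counted from 1 on hg19. A dyad was assigned to a peak when it lay inside it. Adjacent dyads of 1 peak up to 400 bp apart formed pairs, and the most frequent spacing was taken from 5 bp bins after a running mean over 3 bins. The regions named were fixed by a rule before the data were examined: the 10 widest peaks, the 10 bins of 1 Mb with the most peaks, the 5 peaks with the most dyads and the 5 longest runs of dyads spaced 120 to 250 bp.

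The descriptions of the peak set, the nucleosome set, the share of dyads in peaks and the spacing were planned before the data were examined. The planned comparison of occupancy inside and outside peaks gave no value, because no dyad lay outside a peak. Planned analyses of transcription start sites, gene lists, sequence motifs, CTCF sites and dinucleotides were not run, because no hg19 sequence or annotation was used here, and no gene names are attached to regions.

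The 8 tests reported below, their width and distance limits, and the relations across chromosomes were chosen after profiles of the same data had been looked at. Further profiles were looked at and not tested, so the adjusted values cover the 8 reported tests alone and all p-values are descriptive. For 6 tests, a value was computed in each of the 22 autosomes, and a two-sided sign-flip permutation test with 100000 resamples was applied over autosomes. For the clustering of wide peaks, widths were permuted among the peaks of each chromosome 1000 times (one-sided). For the 10 bp component of spacing, each autosome's component was taken along the phase of the other autosomes and compared with 1000 sets of spacings drawn from smoothed curves without the component (two-sided). A sign-flip test was first used for this component and was replaced after simulation, because it gave p under 0.05 in 29 of 200 sets drawn without any component (14.5%). Autosomes are parts of 1 pooled data set and not biological replicates, so each p describes this data set and not variation between cultures. The Benjamini-Hochberg adjustment was applied over the 8 tests and, separately, over the 8 relations across chromosomes.

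The procedures were tested on simulated dyads placed in the real peaks. A planted 10 bp component of 0.1 was recovered as 0.105, and a planted occupancy difference of 0.15 as 0.147. In 5 simulated sets with no effect, neither of these 2 tests gave a p under 0.05, and the smallest values were 0.1 and 0.15. The number of simulated pairs was lowered after a first run to bring it near that of the data. For this, each peak was given dyads with a probability of 0.2, whereas 77.3% of peaks had a dyad in the data. Simulated occupancies were drawn independently, so dependence between neighbouring dyads was not covered. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.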

Results

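Accessible chromatin and nucleosome positions were mapped in BJ fibroblasts with 8 technical replicate ATAC-seq libraries of 1 group. The deposited tables give no values per library, so no value has a spread between replicates, and the read depth is unknown. Spreads below are SDs over the 22 autosomes.

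The deposited peaks of BJ fibroblasts numbered 162298 and covered 232.5 Mb. None was narrower than 500 bp, and no gap between neighbouring peaks was shorter than 561 bp. The rule that set the peak edges is not given in the sources used here, and distances from edges and midpoints depend on it. Peaks described below as narrower than 800 bp were thus 500 to 800 bp wide. The median peak was 1008 bp wide, and 37.3% of peaks were narrower than 800 bp. The widest 10% of peaks held 30.1% of the covered bases. Autosomes carried 56.0 ± 7.04 peaks per Mb (n = 22), from 38.5 on chromosome 21 to 66.6 on chromosome 17.

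The widest peak spanned 56.0 kb on chromosome 7 (128466590 to 128522623) and held 73 dyads. It was followed by peaks of 53.9 kb on chromosome 2 (216213976 to 216267827), 51.0 kb on chromosome 7 (130548269 to 130599294) and 47.1 kb on chromosome 2 (36578322 to 36625456). A peak of 45.4 kb lay on chromosome 7 (94020778 to 94066140) and 1 of 41.7 kb on the same chromosome (27199868 to 27241528). The remaining members of the 10 widest were on chromosome 17 (48246005 to 48285334), chromosome 2 (36663297 to 36702093 and 36626183 to 36662576) and chromosome 5 (151036174 to 151067357). Chromosomes 2 and 7 each held 4 of the 10. Among the 100 widest peaks, chromosome 7 held 12 where its share of all peaks gives 5.22, but no chromosome passed Fisher's exact test after adjustment (two-sided, lowest adjusted p = 0.14).

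Of these, 3 neighbouring peaks on chromosome 2 formed a stretch of 123.8 kb (36578322 to 36702093) of which 98.8% was covered by peaks. The gaps between them were 720 and 726 bp, and the stretch held 129 dyads. The map of this stretch was drawn after its position had been seen.

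**Figure D1:**
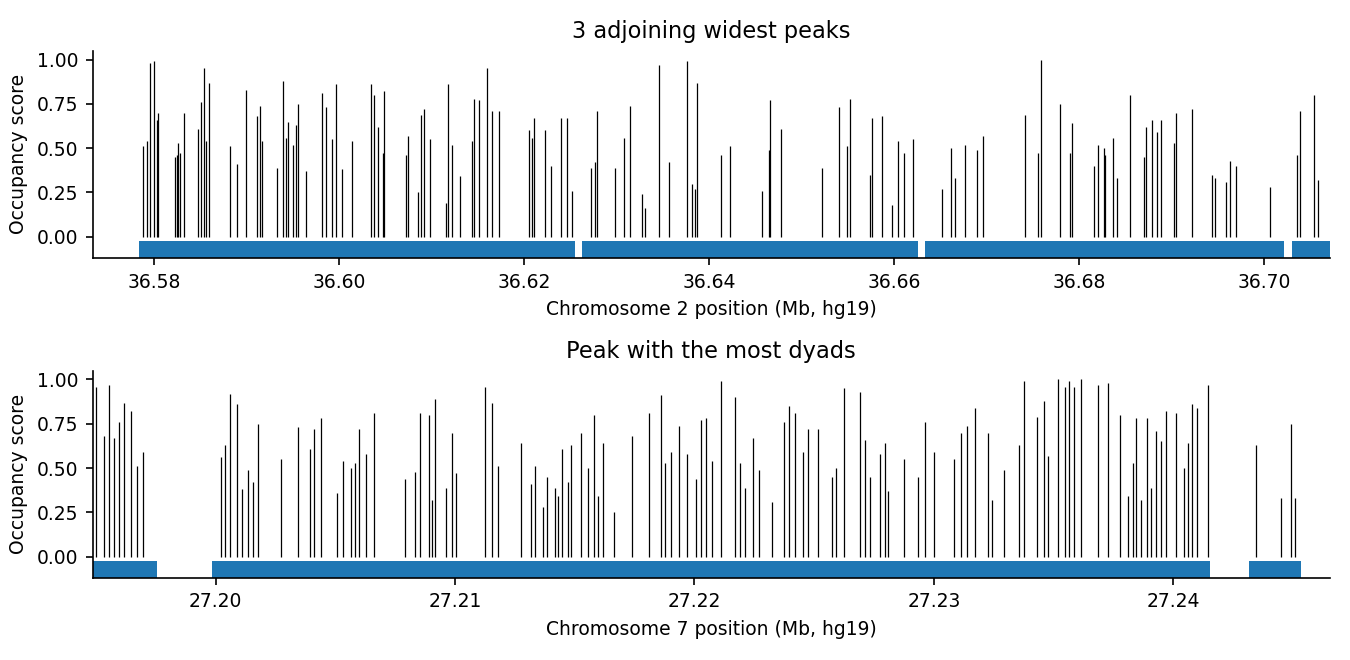
Called dyads (vertical lines, height is the occupancy score from 0 to 1) and peaks (blue bars) along hg19 positions in Mb, for the 3 neighbouring wide peaks on chromosome 2 and for the chromosome 7 peak with the most dyads. The chromosome 2 stretch held 129 dyads in 123.8 kb and the chromosome 7 peak 120 dyads in 41.7 kb.

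Wide peaks lay near one another. Of the 3387 peaks of at least 5000 bp, 44.3% had another such peak within 50 kb, against 18.4% ± 0.872 (SD over 1000 draws) when widths were permuted among the peaks of each chromosome. The permutation p was 0.001 (adjusted p = 0.001), the smallest that 1000 draws can give.

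Peaks were most crowded on chromosome 11 between 12 and 13 Mb, where 148 peaks covered 252.6 kb. Chromosome 5 at 148 to 149 Mb held 146 peaks, chromosome 3 at 149 to 150 Mb held 144, and chromosome 1 at 201 to 202 Mb and chromosome 9 at 124 to 125 Mb held 137 each. The other bins among the first 10 were chromosome 2 at 238 to 239 Mb and at 20 to 21 Mb, chromosome 8 at 134 to 135 Mb, chromosome 7 at 116 to 117 Mb and chromosome 11 at 102 to 103 Mb, with 132 to 136 peaks. The median bin with a peak held 63.

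Nucleosomes were called at 353631 dyads, or 1.52 per kb of peak. The mean occupancy score was 0.667 (SD over dyads 0.212), and 78.0% of dyads scored 0.5 or more. At least 1 dyad was called in 77.3% of peaks, and 36776 peaks had none. All dyads lay inside peaks, none within 60 bp of a peak edge, and no 2 dyads were closer than 120 bp. Whether calling was confined to peaks is not given in the sources used here, so the share inside peaks may have been fixed by the calling and carries no test.

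The peak with the most dyads was the one on chromosome 7 at 27199868 to 27241528, with 120 dyads, or 2.88 per kb. It was followed by 77 dyads each on chromosome 6 (100890838 to 100919369) and chromosome 7 (94020778 to 94066140), and by 75 on chromosome 12 (114830517 to 114855494). The widest peak of all ranked next with 73 dyads at 1.30 per kb.

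Dyads were less occupied in wide peaks than in narrow ones and lay more densely. The difference in density was not detectable once peak edges and dyads of occupancy under 0.5 were both left out. Peaks of at least 5000 bp held 1.66 ± 0.175 dyads per kb, against 1.27 ± 0.0696 in peaks of 600 to 1000 bp, and were higher in 22 of 22 autosomes (3358 and 56035 autosomal peaks). Their mean occupancy was 0.626 ± 0.0205, against 0.688 ± 0.0141, and was lower in 22 of 22 autosomes. Both differences gave p = 1e-05 (adjusted p = 1.3e-05) in the sign-flip permutation test, the smallest that 100000 resamples can give. The difference in density was 0.392 dyads per kb, but 0.187 with dyads of occupancy 0.5 or more and 0.243 against peaks of 1000 to 1500 bp. Leaving out the 60 bp at each edge, where no dyad was called, it was 0.182 (20 of 22 autosomes, permutation p = 2e-05), and with occupancy of 0.5 or more as well it was 0.0158 ± 0.101, not detectable (10 of 22 autosomes, permutation p = 0.48).

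In peaks narrower than 800 bp, dyads stood on both sides of the midpoint and were rare at it. There were 2.88 ± 0.215 dyads per kb at 100 to 150 bp from the midpoint and 0.390 ± 0.0454 within 50 bp of it (17311 and 2380 autosomal dyads). The dyads that were called at the midpoint had a lower occupancy, 0.558 ± 0.0263 against 0.718 ± 0.0175. Both differences had the same direction in 22 of 22 autosomes (sign-flip permutation p = 1e-05, adjusted p = 1.3e-05).

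The arrangement was the opposite in peaks of 800 to 1000 bp, a class set apart after the profiles had been seen. There the midpoint held 1.99 dyads per kb against 1.18 at 100 to 150 bp, and its occupancy was 0.717 against 0.639. Both differences were reversed in 22 of 22 autosomes (permutation p = 1e-05). Dyad density in this class had maxima at the midpoint and at 220 to 240 bp, the latter at 2.52 per kb, and in peaks of 1000 to 1500 bp it varied less with position.

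**Figure D2:**
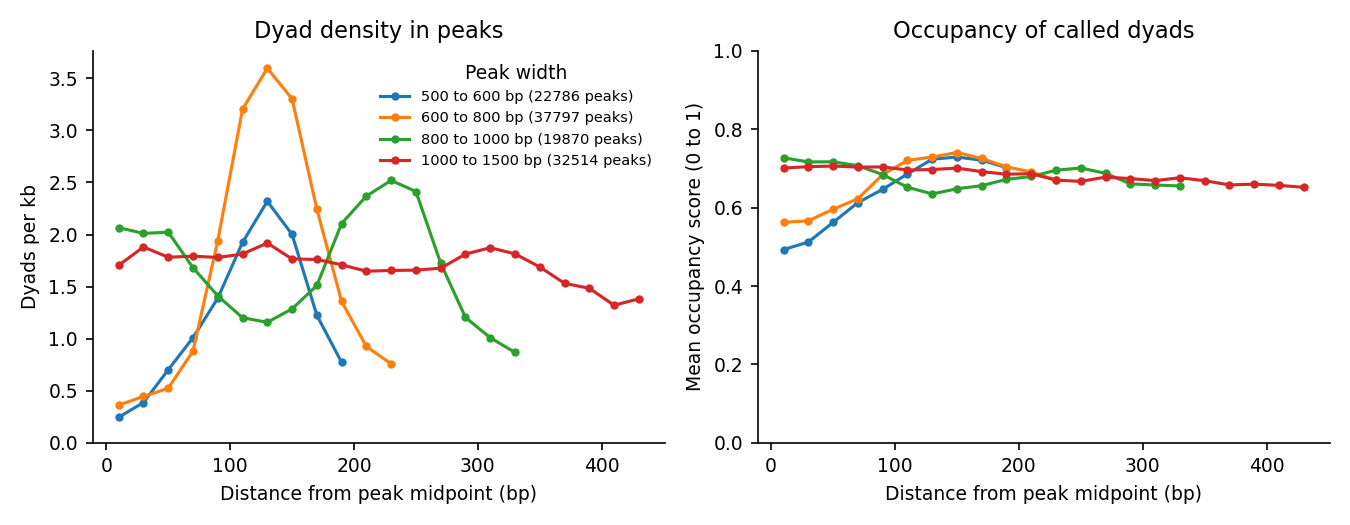
Dyads per kb (left) and mean occupancy score from 0 to 1 (right) by distance from the peak midpoint in bp, in 20 bp bins; each line is a class of peak width over all chromosomes. Peaks of 600 to 800 bp were densest in dyads at 120 to 140 bp, from 5439 dyads, where peaks of 800 to 1000 bp had a local low between maxima at the midpoint and at 220 to 240 bp.

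From the edges of the 66330 peaks of at least 1200 bp, dyad density rose to 3.14 per kb at 220 to 229 bp, fell to 1.09 at 310 to 319 bp and rose again to 2.45 at 420 to 429 bp.

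Adjacent dyads were most often 207 bp apart (SD over autosomes 5.60 bp; 151812 pairs). In peaks narrower than 800 bp the most frequent spacing was 282 bp (SD 8.73 bp; 8895 pairs), and 34.8% of pairs were 260 to 300 bp apart. Peaks of 800 to 1000 bp also had a mode of 282 bp (7636 pairs), and peaks of 800 to 2000 bp had a second maximum at 284.5 bp. In peaks of 2000 to 5000 bp, where the mode was 207 bp, 14.8% of pairs were 260 to 300 bp apart. These spacings were not tested against each other. Among all pairs of dyads up to 1000 bp apart, numbers rose again at 380 to 399 bp, 5.03% above the low at 340 to 359 bp.

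The longest run of dyads spaced 120 to 250 bp lay on chromosome 2 (162270663 to 162273257), with 14 dyads at a mean spacing of 199.5 bp. Runs of 12 dyads lay on chromosome 6 (114290821 to 114293122 and 147525208 to 147527432), and runs of 11 on chromosome 3 (25823657 to 25825595) and chromosome 12 (114833921 to 114835940). The run on chromosome 12 lay in one of the peaks with the most dyads. Runs of at least 10 dyads numbered 14.

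The spacing histogram had steps of about 10 bp, with maxima at 151, 161, 171, 181, 190, 200, 208 and 218 bp. The 10 bp component at spacings from 150 to 240 bp was 0.0913 ± 0.0589 of the smoothed count (61173 autosomal pairs) and positive in 20 of 22 autosomes. Simulated draws without the component reached at most 0.0445. The p from these draws, which is not from a permutation test, was 0.001 (adjusted p = 0.001), the smallest that 1000 draws can give. The exceptions were chromosome 18 at -0.416% and chromosome 21 at -8.88%, the latter with 275 pairs. The period with the largest amplitude was 9.9 bp.

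**Figure D3:**
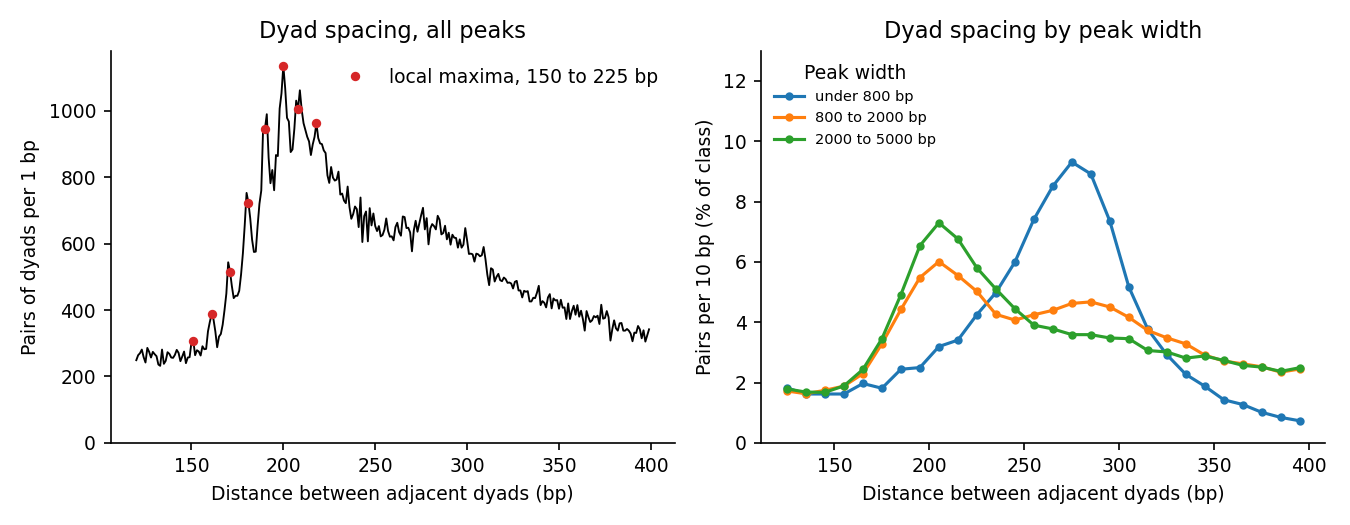
Pairs of adjacent dyads by spacing in bp, per 1 bp over all peaks (left, red points mark local maxima of a running mean over 3 bp) and in 10 bp bins as a percentage of each class of peak width (right). The overall mode was 207 bp and that of peaks under 800 bp was 282 bp.

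Dyads closer than 150 bp were less occupied than regularly spaced ones. Their mean occupancy was 0.568 ± 0.0146, against 0.666 ± 0.0128 for pairs 190 to 210 bp apart, lower in 22 of 22 autosomes (7678 and 19543 pairs). The occupancies of the 2 dyads were negatively correlated in close pairs, with Pearson's r = -0.170 ± 0.0719 (-0.0880 among dyads of occupancy 0.2 or more), and positively in pairs 220 to 300 bp apart, with r = 0.115 ± 0.0354. The correlation was lower for close pairs in 22 of 22 autosomes (21 of 22 among dyads of occupancy 0.2 or more), and both differences gave a sign-flip permutation p of 1e-05 (adjusted p = 1.3e-05). The scores of close pairs summed to more than 1 in 66.8% of pairs, so the 2 scores cannot be read as shares of molecules that exclude each other.

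**Figure D4:**
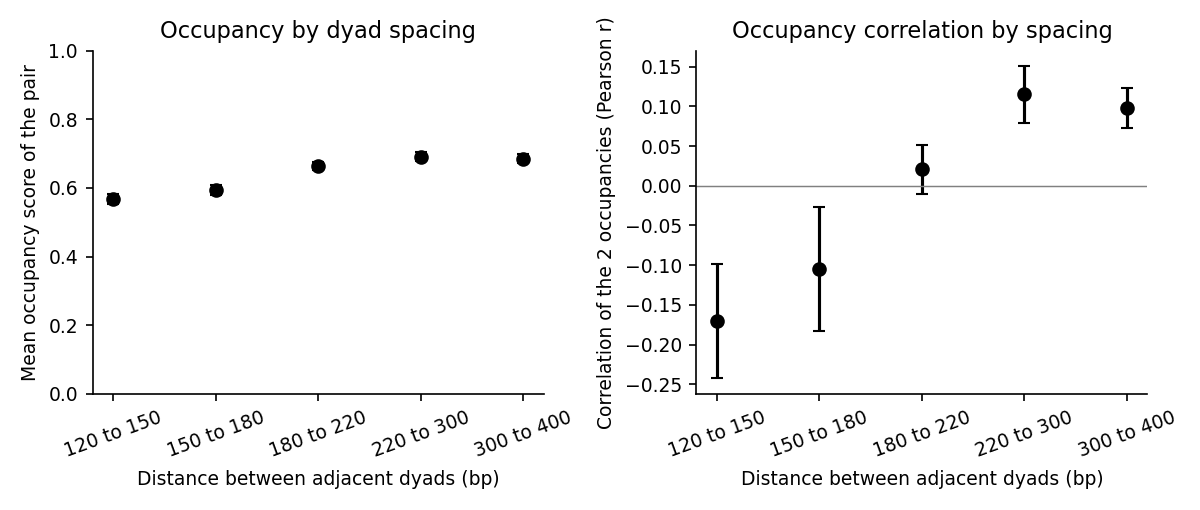
Mean occupancy score of pairs (left) and Pearson correlation of their scores (right) by spacing class in bp; points are means and bars SDs over 22 autosomes. The correlation went from -0.170 at 120 to 150 bp to 0.115 at 220 to 300 bp.

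Shorter autosomes had fewer dyads per kb of peak. The lowest values were 1.25 on chromosomes 21 and 22 and the highest was 1.60 on chromosome 4. Across the 22 autosomes, the span from first to last peak and dyads per kb had Pearson's r = 0.820 (permutation p = 1e-05, adjusted p = 8e-05) and Spearman's rho = 0.932 (permutation p = 1e-05, adjusted p = 2.7e-05). Without chromosomes 1 and 2, the farthest from the median span, r was 0.895. It was 1 of 8 relations computed, and chromosomes of 1 pooled data set are not independent samples of cells. The span had no detectable relation with peaks per Mb (r = 0.270, permutation p = 0.22, rho = 0.126, permutation p = 0.57).

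**Figure D5:**
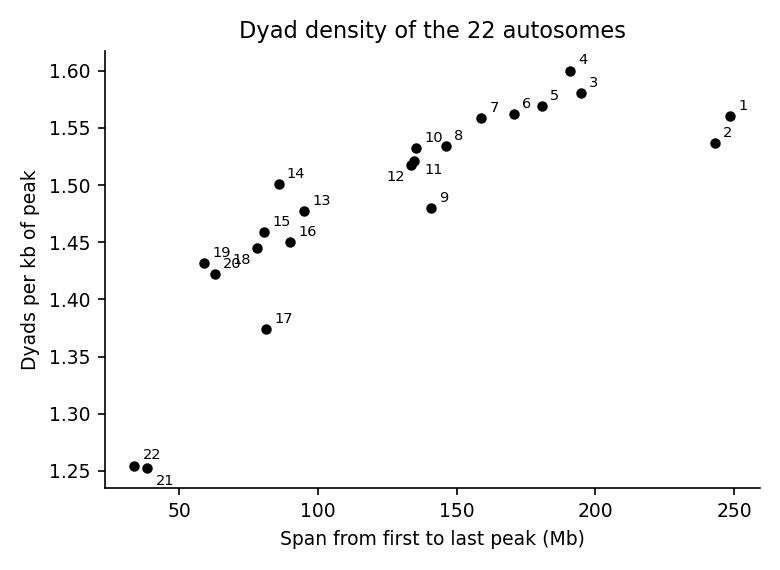
Dyads per kb of peak against the span from first to last peak in Mb; each point is 1 of the 22 autosomes, labelled by number, and the vertical axis does not start at 0. Chromosomes 21 and 22 lay lowest at 1.25 and chromosome 4 highest at 1.60.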

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

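The alternatives for the peak set, nucleosome set, share of dyads in peaks and spacing were fixed before the data were examined; those for the 8 tests were chosen after seeing the data, like the tests themselves. Of the 9 settings fixed in advance, 7 stayed within the limits set, which were 1.5 times for a count, the counting interval for a share and 1 SD over autosomes for a spacing. Keeping only peaks of at least the median width left 81152 peaks and 80.6% of dyads in peaks, both by construction. Some of the 7 could hardly leave the limits either. Counting dyads whose nucleosome footprint overlapped a peak could not lower a share of 100%. Keeping autosomes only left 158160 peaks and 345968 dyads, most of each set. Of the 30 alternatives for the tests, 27 kept the direction and the side of the threshold. The difference in dyad density between wide and narrow peaks fell to 0.0158 per kb (permutation p = 0.48) when the 60 bp at each edge and dyads of occupancy under 0.5 were both left out. That occupancy cut also carries the lower occupancy of wide peaks. The other exceptions were both from peaks of 800 to 1000 bp instead of peaks under 800 bp, where the difference between flank and midpoint was -0.0779 for occupancy and -0.811 dyads per kb for density; the cause was not tested. The result for narrow peaks thus holds for that width class and does not extend to the next. Peaks under 1000 bp as a single class gave 1.68 dyads per kb, which hides the reversal. The comparison of occupancy inside and outside peaks gave no value under any setting, because no dyad lay outside. Alternatives for start sites, gene lists, motifs, CTCF sites and dinucleotides were not run. No paired analysis was possible because there is 1 group and no value per library. Without depth or replicate values, peaks without a dyad cannot be told from peaks with too few reads to call one.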

Other observations

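The tests of explanations in this part were all chosen after the patterns had been seen, and each pattern was found and tested on the same data. The design has 1 group and sets no biological explanation, so none from the design was tested.

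One peak width stood apart: 794 peaks were exactly 631 bp wide, against a median of 233 peaks at each width within 30 bp of it. They occurred on all 23 chromosomes of the table, and 39.4% lacked a dyad, against 42.8% of peaks of neighbouring widths (Fisher's exact test, two-sided, p = 0.065).

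In peaks narrower than 800 bp, and likewise in those of 800 to 1000 bp, adjacent dyads were most often 282 bp apart instead of 207 bp. If peak width set the spacing, it would grow with width at a slope near 1. In peaks of 560 to 800 bp with 2 dyads, the slope was instead 0.137 ± 0.0667 (SD over autosomes). The slope was not tested in peaks of 800 to 1000 bp. If a call were missing between the pair, the favoured spacing would lie near 2 times the main one. In peaks of 600 to 800 bp, however, the spacings that showed the pattern lay at 1.34 ± 0.0339 times. A separate, smaller rise of 75 pairs at 420 to 429 bp leaves missed calls open for those pairs. Missed calls were not tested in peaks of 800 to 1000 bp, so they stay open there. For peaks under 800 bp a candidate explanation is a pair of nucleosomes on either side of an accessible centre: pairs 260 to 300 bp apart were centred on the midpoint, with an offset of 0.359 ± 0.0360 of that of random placement, against 0.80 ± 0.181 for pairs 180 to 220 bp apart (sign-flip permutation p = 1e-05). Dyads in peaks of 600 to 800 bp were densest at 120 to 140 bp from the midpoint (3.60 per kb). The offset therefore largely restates that profile and is not independent support for the explanation. In peaks of 800 to 1000 bp the ratio of the offset to random placement was 0.758 ± 0.0703. Pairs 180 to 220 bp apart had 0.941 ± 0.125 there (sign-flip permutation p = 7e-05). The median offset was 91 bp and the midpoint was rich in dyads, so the explanation stays undecided in this class. The rule asked for a ratio below 0.80 by more than 1 SD. That margin was added after 0.758 had been seen, and without it this class would meet the rule. That the fragments defining a peak also define its dyads was not tested.

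The 10 bp steps in spacing were set against 3 technical explanations. Positions on a grid would make last digits unequal by about the 10.3% amplitude of the steps, but the largest departure was 1.86%. A few chromosomes carrying the steps would leave most others without them, but 20 of 22 had a positive component; and a period in the calling that acts at every spacing would persist at 250 to 340 bp, where the amplitude was 1.10%. Preferred cutting positions of the transposase, and a calling step that acts on short spacings alone, were not tested and stay open, since fragment ends were not used here. Spacing in whole turns of the DNA helix remains a hypothesis.

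Short autosomes had fewer dyads per kb of peak. Narrower peaks on them would leave no relation after standardising widths, but r was 0.787 (permutation p = 3e-05). A few stretches without calls would leave none in the median over 5 Mb bins, but r was 0.737 (permutation p = 9e-05). A larger part near the first or last peak would leave none among bins within 15 Mb of either, but r was 0.682 (permutation p = 0.00036). These argue against each as the whole cause, not as a part of it. The first and last peaks need not mark the chromosome ends, and 7 of 8 bins of chromosome 22 counted as near them. Nearness to the chromosome ends was thus not tested as such. GC content, mappability and read depth per chromosome were not tested and stay open.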
